A study of Mus musculus with 5 samples.

How the data were processed

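The samples were bone marrow-derived dendritic cells of WT and Egr1-deficient C57BL/6J mice, stimulated with LPS and lactic acid. Per the labels' protocols, chromatin was cut enzymatically, precipitated with an antibody against acetylated lysine 27 of histone H3 or against EGR1, and sequenced on an Illumina instrument. Groups were taken from the sample titles, with 1 library each for WT H3K27ac, KO H3K27ac, WT EGR1, WT input and KO input. Called peaks of 3 samples were analysed. The 2 input samples were not analysed here. All samples were stimulated, so no comparison with unstimulated cells or with LPS alone was possible among these samples.

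The authors deposited 1 list of called peaks for each of the WT H3K27ac, KO H3K27ac and WT EGR1 samples, on genome build mm10 per the submitters' processing notes. The aligner, the peak caller, its filters and the use of the input DNA are not given in the sources used here. Per the file headers, each peak has a region, a centre, a length, a peak shape score and a p-value from the authors, and the neighbouring gene on each side with its distance. The deposited p-value is 0.05 or lower in every list. It equals the upper tail of a normal distribution at the score, within the rounding of the values, for all 857, 844 and 847 peaks. How the authors scaled the deposited score in each library is not given in the sources used here, so its size was not compared between lists beyond description. Since peaks were called per library at a threshold, a peak just above it in 1 list can fall just below it in another. The lists hold no counts, so depth is unknown, and 95% Wilson intervals on shares cover counting error over peaks only.

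Positions are given as deposited, counted from 1 with both ends included. Peaks of 2 lists were called overlapping when they shared at least 1 bp (bedtools 2.31.1). Observed overlaps were set beside 1000 random placements of the first list's peaks on the same chromosomes, within the span from the first to the last annotated gene or peak, and beside 1000 placements at the ends of protein-coding genes, both with a fixed seed. The placements keep no clusters together and do not exclude assembly gaps or repeats. The share of WT-only and of KO-only H3K27ac peaks that overlapped an EGR1 peak was counted. The Fisher's exact test fixed for this contrast is not reported, since the definition of KO-only peaks and the overlap of the EGR1 and WT H3K27ac lists largely set its outcome. Scores, centres and lengths were compared over peaks that overlapped exactly 1 partner in each direction. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

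Genes were taken from the authors' neighbouring-gene columns, with a distance of 0 read as a peak inside the gene as the authors place it. A table of RefSeq genes of the same assembly as mm10 gave gene types and coordinates. Of its 49997 genes, 365 whose coordinates did not belong to a placed chromosome sequence were left out, which left 49632 genes, 21787 of them protein-coding. Of the 1025 gene names in the WT H3K27ac list, 689 matched a symbol of this table, and 22 more were among its older symbols. Of the pairs of a peak and a gene at distance 0 whose gene is in this table, 210 of 246 in WT H3K27ac, 211 of 246 in KO H3K27ac and 208 of 245 in EGR1 overlapped by RefSeq coordinates, so some genes with a peak inside rest on the authors' annotation alone. The names that did not match stayed as the authors gave them. The table gives no strand, so the window of 2 kb around a transcription start fixed before the data were examined was replaced by 2 kb around either end of a protein-coding gene. The share of peaks within 500 kb of an end of the span was added to describe location. No genome sequence was used here, so the planned search for the EGR motif was not run.

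Members of 15 gene lists fixed before the data were examined were counted when a peak lay in the gene or within 2 kb of it. The lists covered LPS-induced cytokines and chemokines, NF-kB and MAPK feedback, interferon response, dendritic cell maturation, dendritic cell and myeloid identity, EGR family and immediate early genes, glycolysis and hypoxia, lactate- or IL-4-associated genes, 5 sets of markers of other blood cells, housekeeping genes, and neuronal and germline genes. Each count was compared with all other protein-coding genes by a one-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 15 lists within a library. Members that the RefSeq table does not hold as protein-coding genes were left out of this test. Genes are units of 1 library in this test and not replicates. The genes named in the text are those beside the 10 highest-scoring WT-only, KO-only, shared H3K27ac and EGR1 peaks, list members with a peak in a single H3K27ac list or with an EGR1 peak, at most 4 per list, and 14 genes fixed by name. Genes outside this rule, among them the mitochondrial genes and the examples of housekeeping genes, were chosen after their values were seen.

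The code for both counts was run on simulated data. Of the overlaps planted in the real lists, 600 of 600 were recovered for WT against KO H3K27ac, 593 of 593 for EGR1 against WT H3K27ac and 593 of 593 for EGR1 against KO H3K27ac. Planted peaks were slightly shifted copies of real peaks, and random peaks that overlapped the other list were removed beforehand. Full recovery was thus set by construction and checks the code only. Of 200 gene lists of 30 members simulated with 10 carrying a peak, 200 passed an unadjusted threshold of 0.05, and of 200 lists drawn at random 1 did. A list of 30 genes reaches an unadjusted p of 0.0181 with 2 members carrying a peak and 0.00113 with 3. Alternatives were an overlap of at least 50% of both peaks, a distance of up to 1 kb, the highest-scoring 50% of each list, lists of equal length, autosomes and X only, and gene windows of 1, 5 and 50 kb. Loci merged within 10 kb, chromosome spans set by RefSeq genes alone and RefSeq coordinates for the gene lists were added after the data were seen.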

Results

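Chromatin immunoprecipitation and sequencing (ChIP-seq) was carried out on bone marrow-derived dendritic cells of C57BL/6J mice. The cells were grown from femoral marrow with 10 ng/ml GM-CSF, the growth factor that drives dendritic cell differentiation in culture, and collected on day 6. All 5 samples were then stimulated for 24 h with 100 ng/ml lipopolysaccharide (LPS), the bacterial ligand of Toll-like receptor 4, together with 20 mM lactic acid. Acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, was precipitated from wild-type (WT) cells and from cells lacking Egr1 (KO). EGR1, a zinc finger transcription factor of the immediate early response, was precipitated from WT cells. Each of these 3 samples was represented by 1 list of called peaks, and the remaining 2 samples, input DNA of each genotype, were not analysed here. With 1 library per group there was no replicate check, and no difference between lists could be tested as an effect of genotype. The lists hold no read counts, so the depth of each library is unknown.

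The WT H3K27ac list held 857 peaks, the KO H3K27ac list 844 and the WT EGR1 list 847, on mm10. Each peak carries a peak shape score and a p-value, which are the authors' own and are used here only to describe or rank peaks within a list. The highest score was 35.26 in WT H3K27ac, 35.48 in KO H3K27ac and 34.62 in EGR1. The median peak length was 324 bp, 310 bp and 323 bp in the same order. In each list many peaks fell in a few dense clusters. The cluster with the most peaks was the interval 3000025 to 3038283 on chromosome 9, inside the predicted gene Gm26870, which held 53 peaks of WT H3K27ac, 60 of KO H3K27ac and 54 of EGR1.

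**Figure D1:**
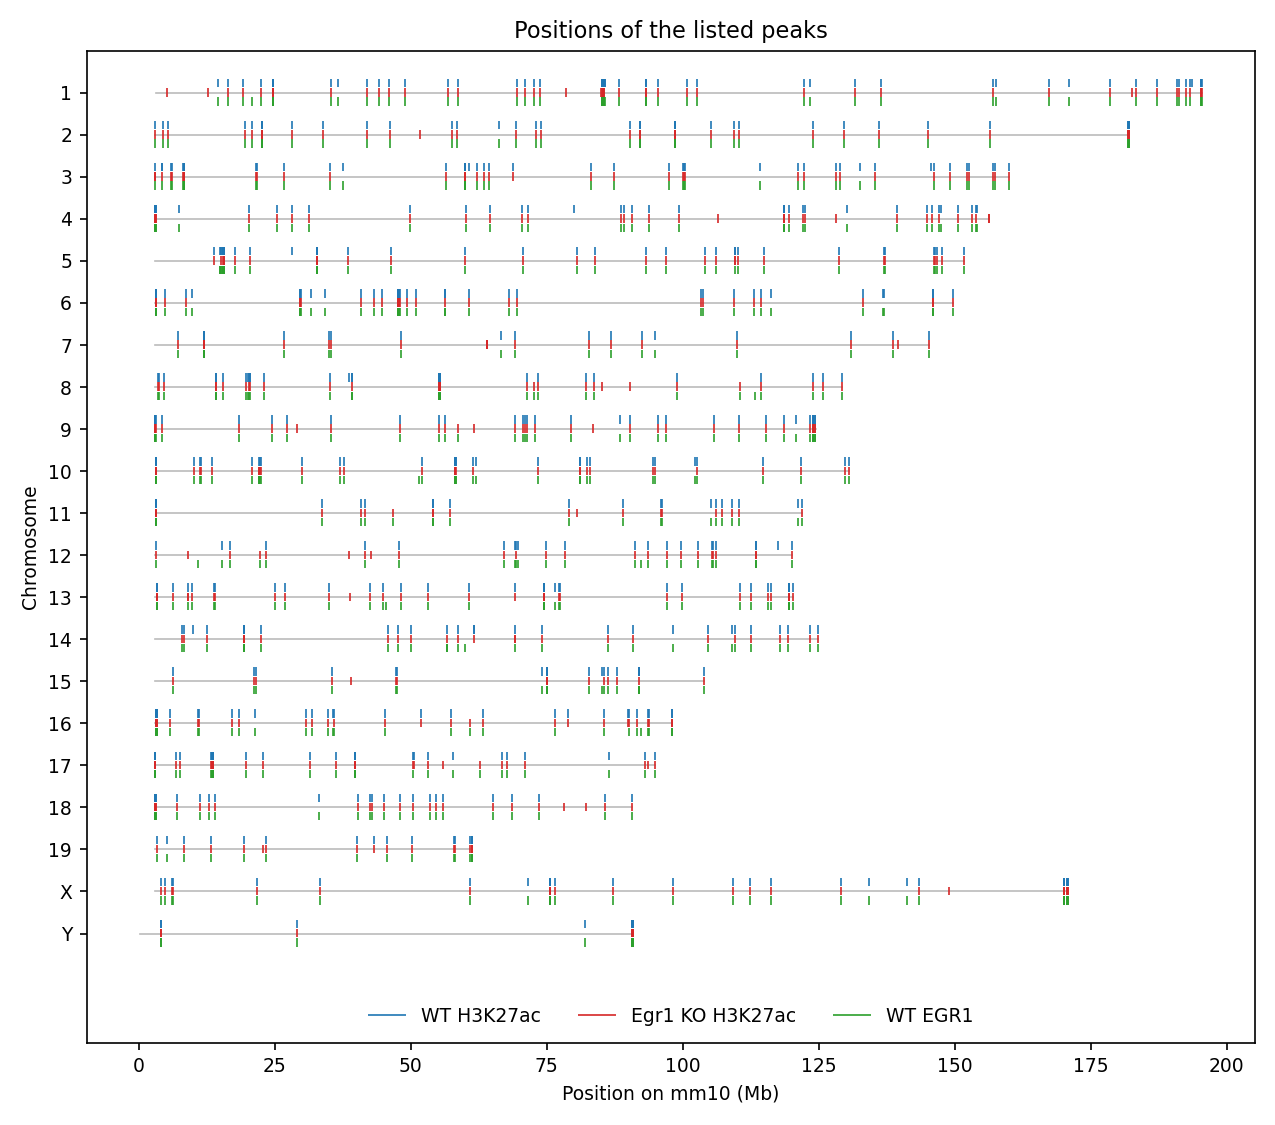
Position of each listed peak along chromosomes 1 to 19, X and Y (x axis, Mb on mm10; y axis, chromosome), with a tick per peak for WT H3K27ac (blue, 857 peaks), Egr1 KO H3K27ac (red, 844 peaks) and WT EGR1 (green, 847 peaks), on a grey line that spans the annotated genes and peaks of each chromosome. Most positions carry ticks of all 3 colours, and the 3 peaks per list on the mitochondrial DNA are not drawn.

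The H3K27ac lists of WT and Egr1-deficient cells were compared first, which asks whether the same regions are listed when Egr1 is missing. With 1 library per genotype and no read counts, the level of acetylation was not compared. The 2 H3K27ac lists held mostly the same regions, led by intergenic and predicted-gene loci rather than by immune genes. The peak with the highest score in both lists lay at 3109836 to 3110154 on chromosome 12, 22794 bp from Gm9075, and scored 35.26 in WT and 35.48 in KO. Next in WT came a peak inside AC160116.1 on chromosome 9 (35305250 to 35305573), with scores of 33.17 and 32.57, and a peak inside Gm10801 on chromosome 2 (98663723 to 98664055), with scores of 31.06 and 30.05. Of the 857 WT peaks, 744 overlapped a KO peak, or 86.8% (95% Wilson interval 84.4 to 88.9, counting error only). Of the 844 KO peaks, 745 overlapped a WT peak, or 88.3% (85.9 to 90.3). Random placement of the WT peaks on the same chromosomes gave 0.52 overlapping peaks on average and at most 3 in 1000 placements.

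The other shared peaks among the 10 with the highest WT scores lay outside the genes that the authors name for them. They were 31564 bp from Gm44436 on chromosome 6 (103649021 to 103649346, score 29.11 in WT and 28.64 in KO), 130028 bp from Gm25727 on chromosome 3 (56575441 to 56575763, 27.65 and 24.06) and 826 bp from Gm10801 (98664910 to 98665251, 26.73 and 26.29). The remaining 4 lay at 120028681 to 120029002 on chromosome 12, 27712 bp from Gm27236, at 170758196 to 170758529 on chromosome X, 10988 bp from Gm15069, at 61331263 to 61331582 on chromosome 19, 34193 bp from Gm21060, and at 90602243 to 90602573 on chromosome 18, 16377 bp from Gm20039. Their WT scores ran from 25.91 down to 25.25. All 4 lay within 500 kb of an end of the chromosome's annotated span, and those on chromosomes 12, 18 and 19 ended at its last position. The highest-scoring peak, near Gm9075, also lay within 500 kb of a span end, and the other shared peaks of the 10 did not.

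Most peaks listed in a single genotype had low scores, with 4 KO-only peaks as the exceptions. The 113 WT-only peaks had a median score of 1.81 and a highest score of 2.91, and 90 of them scored under 2. Of the 113, 20 lay within 1 kb of a KO peak. The highest lay at 137002807 to 137003157 on chromosome 6, between Gm44406 and Rerg. The next was inside Wbp11 (136816658 to 136817011 on chromosome 6, score 2.73), which encodes a splicing factor. The next 8 in rank lay near the vomeronasal receptor genes Vmn1r2 and Vmn1r3 (score 2.53), between Gm21860 and Erdr1 on chromosome Y (2.43), in Gm28439 (2.36), in Rn7s1, a gene of the 7SL RNA, beside Rps29 (2.29), near Gm21887 (2.24), in Sfi1 (2.23), in Tusc3 (2.22) and 60643 bp from Gm15065 (2.22). All 10 overlapped a peak of the EGR1 list.

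The 99 KO-only peaks had a median score of 1.79, and 72 scored under 2. Of the 99, 41 lay within 1 kb of a WT peak. The 4 KO-only peaks that scored 3 or more lay in peak clusters that both lists covered. Of these, 3 were inside Gm26870 on chromosome 9, at 3009747 to 3010008 (score 5.67), 3013195 to 3013429 (4.96) and 3024088 to 3024234 (4.06), and lay 166, 152 and 32 bp from the nearest WT peak. The other was on chromosome 4 13474 bp from Vmn1r-ps2 (3090026 to 3090284, score 5), 72 bp from a WT peak. The remaining 6 of the 10 highest lay again in Gm26870 (2.76), 110145 bp from Gm17065 (2.58), in Luzp4 (148878474 to 148878799 on chromosome X, 2.44), in Pisd, which encodes the mitochondrial phosphatidylserine decarboxylase (2.35), near Gm28002 (2.34) and in Sfi1 (2.31). Of all WT peaks scoring 3 or more, 411 of 411 overlapped a KO peak, and of the KO peaks scoring 3 or more 407 of 411 overlapped a WT peak. Under a score of 2 the shares were 53.8% (46.8 to 60.7) of 195 WT peaks and 60.4% (53.2 to 67.3) of 182 KO peaks.

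By the authors' gene distances, 235 genes had a peak inside them, of which 188 had a peak in all 3 lists. Of the assignments in WT H3K27ac that could be checked against RefSeq coordinates, 210 of 246 overlapped the named gene (85.4%). The genes named in the rest of this paragraph were chosen after their values were seen, except Sfi1, Wbp11 and Luzp4. Sfi1, which encodes a centrin-binding centrosome protein, held 23 peaks in WT H3K27ac, 25 in KO H3K27ac and 23 in EGR1. Tmem267 held 12 in each list. Among genes with a single peak, Ank1, which encodes the red cell membrane protein ankyrin 1, had scores of 25.07, 23.16 and 24.44 in the same order, and Litaf, a gene named for its induction by LPS, had 21.43, 20.45 and 21.18. The centrosomal gene Cdk5rap2 had 19.85, 20.55 and 19.53. A peak in WT H3K27ac and none in KO was found in 22 genes, with scores of at most 2.73, among them Wbp11, Trp73 (2.21), a gene of the p53 family, Pacs1 (2.13) and Sos2 (2.05), and 18 of the 22 also held an EGR1 peak. The reverse was found in 16 genes, with scores of at most 2.44, among them Luzp4, Efna5 (1.97), which encodes an ephrin ligand, and Timd2 (1.82), and 3 of the 16 also held an EGR1 peak. Since 822 of the 847 EGR1 peaks overlapped a WT H3K27ac peak, the difference between these EGR1 counts largely restates the overlap of those 2 lists.

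EGR1 peaks were next compared with the H3K27ac peaks of the same genotype. Nearly every EGR1 peak lay on a WT H3K27ac peak. The 10 EGR1 peaks with the highest scores were those for which the authors name Gm9075, AC160116.1, Gm10801 (2 peaks), Gm44436, Gm25727, Gm27236, Gm15069, Gm21060 and Gm20039, the same 10 regions in the same order as the shared H3K27ac peaks. Their EGR1 scores ran from 34.62 at the chromosome 12 peak near Gm9075 to 25.22 at the chromosome 18 peak near Gm20039. Of the 847 EGR1 peaks, 822 overlapped a WT H3K27ac peak, or 97.0% (95.7 to 98.0), against 0.554 on average and at most 4 in 1000 random placements. Random placement at the ends of protein-coding genes gave 0.411 on average and at most 4. The p of 0.000999 from these placements is the smallest that 1000 can give, and every pair of the lists reached it. Since the placements break up clusters and do not exclude repeats, it says nothing particular to EGR1 or to acetylated regions.

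Among peaks matched to exactly 1 partner, the 100 with the highest EGR1 scores were all partners of the 100 with the highest WT H3K27ac scores. Between the 2 H3K27ac lists that number was 95, again among matched peaks only. Over peaks that could be matched to 1 partner, scores of EGR1 and WT H3K27ac had a Spearman rho of 0.987 across 814 peaks, and scores of WT and KO H3K27ac 0.946 across 739 peaks. Peaks are not independent replicates, and no p-value is given for them. The median distance between matched peak centres was 1 bp for EGR1 against WT H3K27ac and 7 bp for WT against KO H3K27ac. KO peaks were shorter than the matched WT H3K27ac peak in 597 of 739 cases, or 80.8%, and over all 739 the median difference in length, KO minus WT, was -12 bp.

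**Figure D2:**
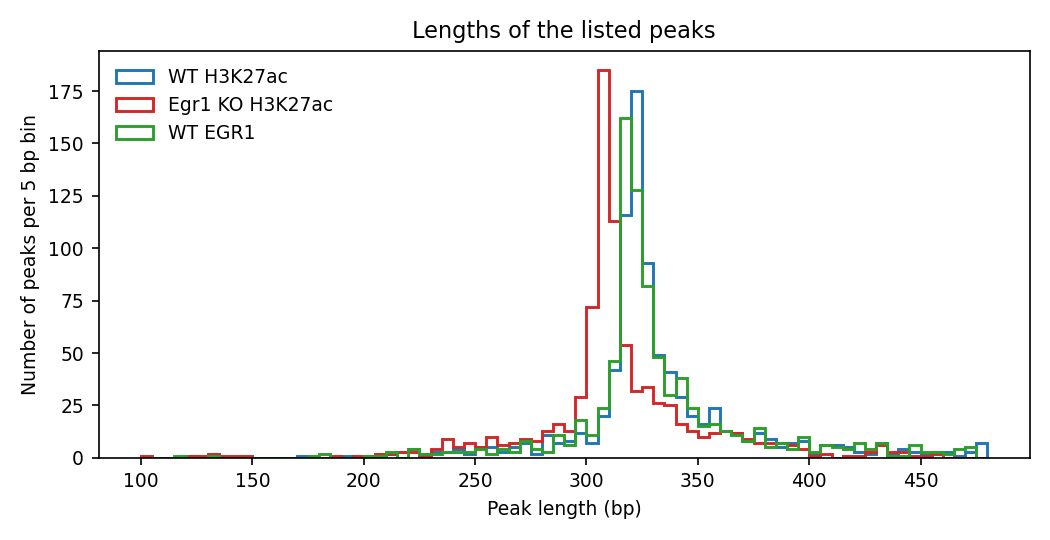
Distribution of peak lengths (x axis, bp, in 5 bp bins; y axis, number of peaks) in the WT H3K27ac (blue), Egr1 KO H3K27ac (red) and WT EGR1 (green) lists. The KO list has its median at 310 bp, below the medians of 324 bp for WT H3K27ac and 323 bp for WT EGR1.

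EGR1 peaks were also compared with H3K27ac in cells lacking Egr1, which asks whether the regions listed for EGR1 in WT cells are listed for the mark without it. Most of them were, led by the regions near Gm9075 and in AC160116.1. Of the 847 EGR1 peaks, 743 overlapped a KO H3K27ac peak, or 87.7% (85.3 to 89.8), against 0.538 on average and at most 3 in 1000 random placements. Of these EGR1 peaks, 731 overlapped peaks of both H3K27ac lists, 91 a WT peak only, 12 a KO peak only and 13 neither. The 91 peaks over WT only had a median EGR1 score of 1.78 and a highest of 2.81, at the region between Gm44406 and Rerg. All 407 EGR1 peaks scoring 3 or more overlapped a peak in each H3K27ac list, the single EGR1 peaks in Ank1 and in Litaf among them.

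EGR1 peaks were also counted within the WT-only, shared and KO-only H3K27ac peaks. Of the 113 WT-only peaks, such as those in Wbp11, Rn7s1 and Tusc3, 92 held an EGR1 peak, or 81.4% (73.3 to 87.5). Of the 99 KO-only peaks, such as those in Luzp4 and Pisd, 13 did, or 13.1% (7.84 to 21.2). Of the 744 shared peaks counted in WT, 730 did, or 98.1% (96.9 to 98.9). WT-only peaks stood 68.3 percentage points above KO-only peaks. KO-only peaks are those that overlap no WT peak, and only 25 of the 847 EGR1 peaks overlapped no WT H3K27ac peak, so this gap restates the overlap of the EGR1 and WT H3K27ac lists and no p-value is given for it.

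**Figure D3:**
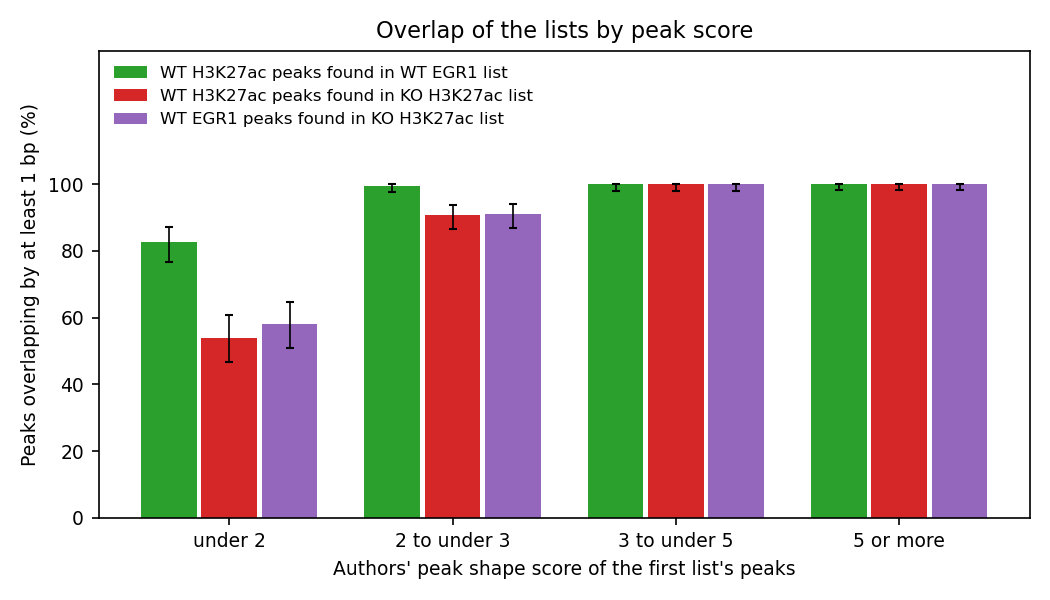
Share of peaks that overlapped another list by at least 1 bp (y axis, percent) by the authors' peak shape score (x axis, under 2, 2 to under 3, 3 to under 5, and 5 or more), for WT H3K27ac peaks found in the WT EGR1 list (green), WT H3K27ac peaks found in the KO H3K27ac list (red) and EGR1 peaks found in the KO H3K27ac list (purple), with 95% Wilson intervals. The bars stand at 82.6%, 53.8% and 57.9% under a score of 2 and at 100% from a score of 3.

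The location of the peaks was then described for each list. Few lay at genes' ends and many lay near the ends of chromosomes. Within 500 kb of an end of the chromosome's annotated span were 25.7% of WT H3K27ac peaks (22.9 to 28.7), 29.4% of KO H3K27ac peaks (26.4 to 32.5) and 25.5% of EGR1 peaks (22.7 to 28.5), while random placements of the WT H3K27ac peaks gave 1.15% on average and at most 2.22%. The cluster in Gm26870 on chromosome 9, a cluster at 3115267 to 3198687 on chromosome 11 with 36 WT H3K27ac peaks, which includes Sfi1, and a cluster at 90760583 to 90807615 on chromosome Y with 22 were of this kind. Counted as loci merged within 10 kb, a choice made after the data were seen, the share in WT H3K27ac was 10.6%. Mitochondrial DNA is shorter than 500 kb, so the 3 peaks on it in each list count as near an end, in the data and in every placement.

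Within 2 kb of an end of a protein-coding gene were 7.70% of WT H3K27ac peaks (6.10 to 9.68), 7.46% of KO H3K27ac peaks (5.88 to 9.44) and 7.67% of EGR1 peaks (6.07 to 9.66). Random placements gave 6.37% on average for WT H3K27ac, and at most 9.80%, so none of these shares was above the range of random placement. Inside protein-coding genes such as Sfi1, Ank1 and Litaf lay 29.4% of WT H3K27ac peaks (26.5 to 32.5), below the lowest of the random placements at 33.5%. Each list also held 3 peaks on the mitochondrial DNA, which carries no histones. In WT H3K27ac they began at position 3918 in mt-Nd2, at 9935 over mt-Nd4l and mt-Nd4, and at 15797 beyond mt-Tp, with scores of 2.04, 1.69 and 2.61.

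Gene lists fixed before the data were examined were used to ask which genes of stimulated dendritic cells carried peaks. By the authors' own neighbouring genes, a single member of the 15 lists, which hold 336 distinct genes, had a peak within 2 kb in each of the 3 libraries, and RefSeq coordinates, a comparison chosen after the data were seen, added a second member, Oasl1. The first was Csf2ra, the alpha chain of the GM-CSF receptor, with a peak inside the gene at 61224334 to 61224651 on chromosome 19 that scored 2.26 in WT H3K27ac, and with scores of 1.91 in KO H3K27ac and 2.17 in EGR1. This peak is among those within 500 kb of an end of the chromosome's annotated span. From the share of protein-coding genes with a peak, 2.28 members were expected in WT H3K27ac. Csf2ra belongs to the dendritic cell and myeloid identity list, for which 1 of 30 members gave a one-sided Fisher's exact p of 0.186 in both H3K27ac libraries and 0.190 in EGR1, with an adjusted p of 1 over the 15 lists (Benjamini-Hochberg). Within 50 kb the same list added Batf3, a transcription factor of conventional dendritic cells, with a peak 11898 bp away that scored 2.79 in WT H3K27ac. In the same window the interferon response list held Oasl2, an antiviral gene, with a WT H3K27ac peak 10128 bp away at 114922363 to 114922685 on chromosome 5. This peak scored 18.13, 17.91 and 18.01 in WT H3K27ac, KO H3K27ac and EGR1. The authors place it inside Gm13822, a gene of a long noncoding RNA. By RefSeq coordinates the same peak lay 458 bp from Oasl1, also a member of the interferon response list, in WT H3K27ac, 466 bp from it in KO H3K27ac and 460 bp in EGR1.

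By the authors' neighbouring genes, which do not name Oasl1, none of the other lists had a member with a peak within 2 kb in any library, and each had a p of 1. This held for 0 of 30 LPS-induced cytokines and chemokines (29 tested), 0 of 30 genes of NF-kB and MAPK feedback, 0 of 30 interferon response genes (28 tested, and Oasl1 had a peak by RefSeq coordinates), 0 of 30 genes of dendritic cell maturation and antigen presentation, 0 of 30 EGR family, cofactor and immediate early genes, 0 of 30 genes of glycolysis, hypoxia and lactate handling and 0 of 30 lactate- or IL-4-associated myeloid genes. It held likewise for 0 of 15 macrophage, 0 of 15 neutrophil, 0 of 15 lymphocyte, 0 of 10 mast cell and basophil and 0 of 10 erythroid and megakaryocyte markers, for 0 of 20 neuronal and germline genes and for 0 of 20 housekeeping genes, among them Actb, Gapdh and Eef1a1, whose promoters are active in most cells. No list member had a peak within 2 kb in 1 H3K27ac library and not in the other. A list of called peaks does not show absence of signal at genes without a peak.

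The 14 genes fixed by name had no peak within 50 kb in any list. They were Egr1, its relatives Egr2 and Egr3, the EGR corepressors Nab1 and Nab2, the transcription factor gene Snai1, the cytokine genes Il12b, Tnf, Il6 and Il10, the costimulatory genes Cd40 and Cd86, the chemokine receptor gene Ccr7 and the p38 kinase gene Mapk14. Egr1 lies at 34861207 to 34864956 on chromosome 18, and its nearest peak was 1748 kb away in WT H3K27ac and EGR1 and 5443 kb away in KO H3K27ac, so the lists do not check the knockout. The nearest WT H3K27ac peak was 549 kb from Il10, 587 kb from Cd86, 915 kb from Egr3 and 1029 kb from Tnf, and 11021 kb from Snai1, the farthest of the 14. For Il12b it was 2767 kb away, and for Il6 1914 kb.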

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

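Merging peaks within 10 kb into loci, spans set by RefSeq genes alone and RefSeq coordinates for the gene lists were chosen after the data were seen, and the other alternatives before. With 1 library per group, no replicate could be left out and no spread between replicates bounds the values. Of 62 alternative values, 32 were counted as unchanged and 30 as moved, and in the cases below the cause was not tested unless stated. A share was unchanged within the counting interval of the reported value, and a gene count within 1.5 times the reported count. The gap between WT-only and KO-only peaks in EGR1 overlap was instead judged by its sign and by the Fisher's exact test that is not reported. The overlap of the lists largely sets the outcome of that test, so the unchanged alternatives of the gap say little about stability. The gap, which restates that overlap, lay between 60.6 and 73.1 percentage points. Counting peaks within 1 kb raised the share of WT H3K27ac peaks found in KO to 89.1% and of KO found in WT to 93.1%, as the wider distance must. In the highest-scoring 50% of each list the shares were 90.7% for WT H3K27ac found in KO, 92.4% for KO found in WT, 98.1% for EGR1 found in WT H3K27ac and 92.2% for EGR1 found in KO. As loci, 92.3% of KO H3K27ac was found in WT. The share within 500 kb of a span end rose to 33.4%, 35.8% and 33.6% in the highest-scoring 50% of WT H3K27ac, KO H3K27ac and EGR1, and fell to 10.6%, 11.4% and 10.4% as loci, since each cluster then counts as 1. With spans set by RefSeq genes alone these shares kept their values of 25.7%, 29.4% and 25.5%. The share near an end of a protein-coding gene was 4.78%, 4.50% and 4.84% with a 1 kb window and 14.4%, 14.0% and 14.8% with a 5 kb window, by the width of the window, and 4.21% for WT H3K27ac and 4.26% for EGR1 in the highest-scoring 50%. The number of gene list members with a peak, 1 in each library, was 0 in the highest-scoring 50%, 3 within 50 kb (Batf3, Csf2ra and Oasl2) and 2 with RefSeq coordinates (Csf2ra and Oasl1). For the EGR motif, the searches fixed beforehand (200 bp around the centre, 1 mismatch allowed, and the highest-scoring 50%) were not run, since no genome sequence was used. Depth is unknown, so a region missing from a list cannot be separated from one that fell below the authors' threshold.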

Other observations

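The tests of fragment length, of the genotype and of centre shifts were chosen only after the results were seen. The bounds for the tests of span ends, gene ends and the score threshold were set beforehand. The share near span ends was an addition to the original plan, and the gene-end window replaced its window around transcription starts.

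Other genes held peaks in all 3 libraries, and those named here were chosen after their values were seen. Smo, which encodes the hedgehog signal transducer, held 3 peaks in each list with best scores of 8.14 in WT H3K27ac, 9.45 in KO H3K27ac and 8.01 in EGR1. Asmt, which encodes the last enzyme of melatonin synthesis, held 2 peaks in each with best scores of 8.91, 9.79 and 8.63. Eef2, a translation elongation factor gene that most cells express, held 2 peaks in each with best scores of 4.30, 4.33 and 4.28. Duxf3 on chromosome 10 held 2 peaks in WT H3K27ac, 4 in KO H3K27ac and 1 in EGR1, with low best scores of 1.74, 2.27 and 1.73. With 1 library per group these differences in number were not tested.

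The EGR1 and H3K27ac lists held nearly the same regions, although one antibody targets a transcription factor and the other a histone mark. EGR1 occupancy of acetylated active promoters is argued against as an account of most of these regions. Of the EGR1 peaks over WT H3K27ac peaks, only 7.66% lay within 2 kb of either end of a protein-coding gene. The bounds set beforehand were over 50% for this explanation and at most 25% against it. Random placement of all EGR1 peaks gave 6.29% on average and at most 9.09%. Regions that yield peaks with any antibody, such as repeat arrays at the ends of the assembled chromosomes, are a candidate explanation: 25.7% of WT H3K27ac peaks lay within 500 kb of a span end, above the highest of 1000 random placements at 2.22%. That share leaves most peaks unaccounted for, and falls to 10.6% when clusters are merged into loci. Other values bear on this explanation without testing it. Each list held 3 peaks on the mitochondrial DNA, which carries no histones. Of the 20 housekeeping genes on the fixed list, 0 had a peak within 2 kb in any library, although Eef2, outside that list, held 2 peaks in each. Occupancy of enhancers away from genes, and the input libraries as a check of these regions, were not tested.

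The WT EGR1 list was closer to the WT H3K27ac list than the KO H3K27ac list was. Among matched peaks scoring 3 or more the median centre shift was 5 bp larger against KO H3K27ac than against EGR1, and the scores had a rho of 0.967 against KO and 0.993 against EGR1, so peaks close to the score threshold do not account for these. For membership the threshold stays open: among WT peaks scoring 3 or more the share found in the EGR1 list exceeded that found in the KO list by 0 percentage points, but both shares were 100%, which decides nothing, and from 2 to under 3 they were 99.6% and 90.8%. DNA fragment length differing between the WT and KO preparations stays open too, since 80.8% of matched KO peaks were shorter than the WT H3K27ac peak, between the 60% and 90% set as bounds. It cannot be told apart from the Egr1 genotype with 1 library per genotype.

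The KO-only H3K27ac peaks with a score of 3 or more, 3 in Gm26870 and 1 listed with Vmn1r-ps2, lay in gaps between peaks that both H3K27ac lists held. For 4 of the 4, the KO peak on each side overlapped the WT peak on that side and no other. No explanation was tested for them.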
